A study of Mus musculus with 24 samples.

How the data were processed

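RNA was measured in primary mouse brain microvascular endothelial cells (MBMECs), the cells that line the capillaries of the brain. The cells were grown on transwell inserts, so that the apical (blood-facing) and the basal side could be treated separately. There were 24 libraries in 6 groups of 4. In 5 groups the cells came from wild-type mice: vehicle, 500 nM of CYM50260 (an agonist of the S1P4 receptor) on the apical or the basal side, and 50 nM of sphingosine-1-phosphate (S1P, a lipid mediator with 5 known receptors) on the apical or the basal side. The sixth group held vehicle-treated cells labelled as global S1P4 knockout. Per the labels' protocols, puromycin was applied for 48 h to remove other cell types, treatment began 48 h after seeding and lasted 24 h, 3 inserts were pooled per sample and 100 ng of RNA went into a stranded mRNA library. The series' design text gives 12 mice per replicate. Whether 2 libraries with the same replicate number came from the same pool of mice is not given in the sources used here.

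The submitters' processing notes name FastQC, Trimmomatic 0.38, STAR 2.7.3a, featureCounts 1.6.5 from Subread, DESeq2 1.26.0 and the mm10 genome build. They give no role or order for these tools, and the strand setting and the handling of duplicate reads are not given in the sources used here. The authors deposited 1 table for the wild-type libraries and 1 for the knockout libraries. The values in both deposited tables are a signal per gene, in whole numbers: gene counts divided by 1 factor per library and then rounded. This was read from the values: in each library whole numbers are missing or doubled at regular steps, and the totals were nearly equal. They are called normalized counts below. The steps gave an estimate of 3.93 to 5.54 M reads on genes per wild-type library and of 17.9 to 21.1 M per knockout library, while the normalized totals were 4.49 to 4.72 M and 17.4 to 17.8 M. The rounding kept the reads themselves from being recovered, so no count model was used. The design written before the data were examined assumed a count model and named the limma test used here for the case of normalized values.

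The wild-type table held 18091 genes and no mitochondrially encoded gene. The knockout table held 36326 rows for 18297 genes, of which 18029 genes stood on 2 identical rows, and 1 row was kept for each. The tables shared 16765 genes, and 99.1% of wild-type genes but 72.6% of knockout genes had the start and end of GENCODE M21 (mm10). Because the tables were normalized separately and used different gene models, no test was made between them, and the planned agreement of knockout and agonist effects was not computed. Coordinates below are on mm10, as in the wild-type table.

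Genes with a mean normalized count of at least 10 over the 20 wild-type libraries were tested (12249 genes). Log2(value + 1) was fitted with limma 3.58.1 (R 4.3.3) as group means over all 20 libraries with a mean-dependent prior variance, and p-values were adjusted by Benjamini-Hochberg over genes, with calls at an adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, with the standard error (SE) of the limma fit. Abundant genes were compressed in the wild-type table, as described in the closing part, so their fold changes may be understated too. Small fold changes of abundant genes may also follow the factor of each library. Before the data were examined, 35 gene lists were fixed. The 33 with at least 3 tested genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and the 2 others were the mitochondrially encoded genes and the erythroid markers, of which the wild-type table held 0. The rule for named genes was also fixed: the S1P receptors, up to 8 called genes per direction with separate groups, up to 4 members of each called list, and the 5 genes with the smallest p where fewer than 5 passed. For basal S1P against the other treatments together, Casz1 fell outside that rule, because its groups overlapped. It was chosen there after its values were seen, because the count it belongs to was small.

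The fits were tested on simulated data for the comparison of basal S1P with vehicle over 12249 genes, with 200 genes changed in each of 5 repeats. In the first simulation the differences between libraries were redrawn for each replicate number, and group means recovered 53.2% of genes changed 1.5-fold, 77.2% at 2-fold, 92% at 3-fold and 95.2% at 4-fold. A second simulation, added after the first had been seen, kept the differences as observed, and there 53.2%, 77.2%, 92% and 93.2% were recovered. In both, group means gave 0 false calls with no gene changed and at most 2 per repeat with changed genes. In the second simulation camera at the preset correlation found the 1 planted list in all 5 repeats but also called 25 other lists in total, against 0 with an estimated correlation, while in the first it called 0 others either way. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.

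Replicates were compared before averaging: 0 of the 30 pairs within wild-type groups held identical values, and their chi-square per gene ranged from 1.40 to 13.3. Whether replicate numbers pair the samples was checked with the correlation across genes of deviations from the group mean. Between vehicle and agonist apical, agonist basal or S1P apical the same-number correlations ranged from 0.375 to 0.777, above the 0.1 set as the rule. Vehicle replicate 3 still matched S1P apical replicate 4 best (0.705, against 0.375 with its own number), so for S1P apical the pairing is not clear. Vehicle replicate 2 matched agonist apical replicate 1 best (0.589, against 0.428 with its own number), so for agonist apical the pairing is not clear either. The fit with the replicate block called 0 genes in each of these 3 comparisons, as did the fit without it. For S1P basal not every number paired, and its blocked counts stand in the closing section. The alternatives were library totals as scaling, quantile normalization, no filter, a filter of 1 CPM in 4 libraries, pseudocounts of 0.1 and 10, the replicate block, only the groups compared, a change of at least 1.5 times and each replicate left out. Those added after seeing the data were sex-linked genes, summed pericyte markers, the sums of pericyte, smooth muscle and fibroblast markers, or 1 to 6 principal components as covariates, and both S1P libraries that stood apart left out. Component 4 separated basal S1P from all other groups, so fits with 4 or more components were not counted among the alternatives of single genes. Directions of the lists named below were compared under all 3 scalings, and the median of all genes moved by less than 0.1 on the log2 scale. Ratios of gene lists between the tables were computed and are not interpreted: the cytosolic ribosomal proteins stood 3.17 log2 units above genes of like count per base.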

Results

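Poly(A) RNA of wild-type MBMECs was sequenced after 24 h with vehicle, the S1P4 agonist or S1P, in 20 libraries, and 4 vehicle-treated libraries labelled S1P4 knockout, called knockout below after that label, were added for comparison. The series' design text calls basal S1P barrier-opening, and apical S1P and both agonist treatments barrier-tightening. Each wild-type library held 4.49 to 4.72 M normalized counts, with 1009 to 1952 genes at 0. Each replicate came from 12 mice, but no source used here ties single libraries to separate pools, so the p-values measure the spread between these libraries. Intervals from counting alone are not given, because the reads behind the values were not recovered.

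S1pr4 (ENSMUSG00000044199), the gene of the receptor S1P4, was detected in every library, including those labelled knockout. It lies on chromosome 10 from 81497747 to 81500132 on the minus strand. Its mean in the wild-type vehicle libraries was 150 ± 28.4 normalized counts (SD, n = 4), and the libraries labelled S1P4 knockout held 250, 261, 349 and 260. The tables were normalized separately, so no test was made; relative to genes of like count per base S1pr4 lay at -0.07 on the log2 scale, at percentile 41.4 of all genes. Which part of the gene was deleted is not given in the sources used here, and per M normalized counts S1pr4 was at 15.9 ± 2.63 in knockout and 32.8 ± 6.52 in wild-type vehicle (SD, n = 4 each), so whether it was lower depended on the scaling. Per M the lower value was not particular to S1pr4: S1pr2 was at 5.79 against 16.4, Cpm at 51.3 against 124 and Atoh8 at 27.6 against 55.5. The more abundant S1pr1 was higher per M, at 725 against 315. S1pr5 had no value in either table. Among the other receptors, S1pr1 was the highest in wild-type vehicle at 1443 ± 230 (SD, n = 4), followed by S1pr2 at 74.8 ± 18.7 (SD, n = 4) and S1pr3 at 41.8 ± 29.7 (SD, n = 4). Per exonic base S1pr2 and S1pr3 were alike, at 0.00938 and 0.00935. No treatment moved S1pr1, S1pr2, S1pr3 or S1pr4 past the threshold. The log2 change of S1pr4 was 0.03 ± 0.16 (SE) with apical agonist, -0.08 ± 0.16 with basal agonist, 0.04 ± 0.16 with apical S1P and -0.05 ± 0.16 with basal S1P.

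The wild-type libraries differed from each other mainly by replicate. The first principal component held 43.6% of the variance and the second 21.2%, and replicate number accounted for 83.9% and 59.6% of their scores, against 5.95% and 12.0% for treatment group. The non-coding RNA Xist, made from the inactive X chromosome of female cells, was at 1, 2251, 1063 and 190 normalized counts in vehicle replicates 1 to 4. Markers of other vascular cells also differed between these replicates, but did not follow Xist. Col1a1, a fibroblast collagen, was at 167, 260, 12 and 16, and Rgs5, a pericyte gene, at 358, 329, 90 and 29. Some numbers did not match. S1P apical replicate 3 and S1P basal replicate 2 had 525 and 552 of Xist, unlike every vehicle library, and S1P apical replicate 4 had 1417. Agonist apical replicate 2 had 1382, against 2251, 2507 and 2555 in replicate 2 of vehicle, agonist basal and S1P apical.

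**Figure D1:**
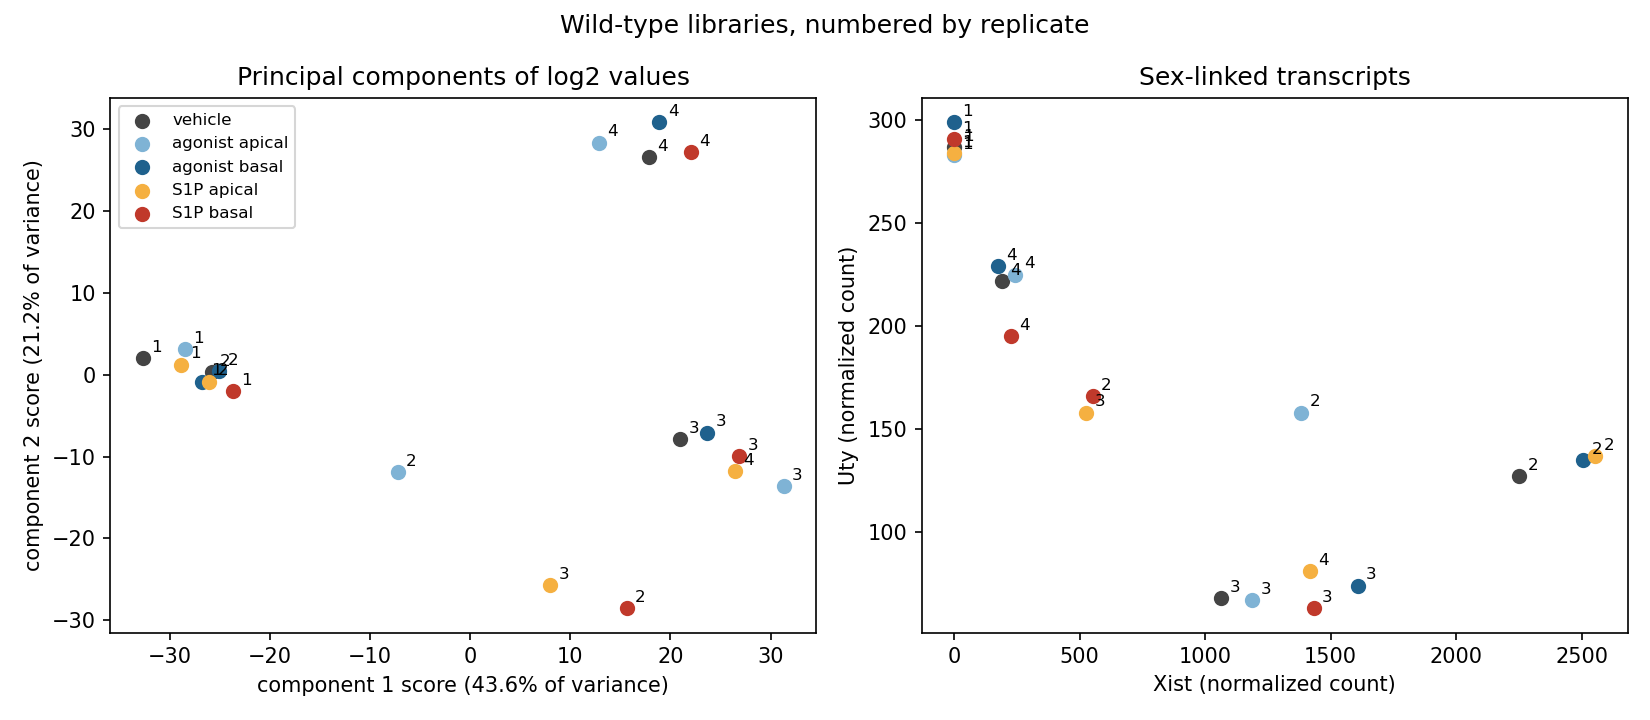
Left, scores of the 20 wild-type libraries on the first and second principal component of log2 values; right, normalized counts of Xist and of the Y-linked gene Uty, with colours for treatment and numerals for replicate. Most libraries lie by replicate number, while S1P apical replicate 3 and S1P basal replicate 2 lie beside each other.

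The comparison of basal S1P with vehicle asks which genes respond to the barrier-opening treatment. Ackr4, Atoh8 and Cpm fell with basal S1P, and no gene rose past the threshold (3 of 12249 genes, limma). Ackr4 (ENSMUSG00000079355), a scavenging receptor for the chemokines CCL19 and CCL21, fell by 1.33 ± 0.21 (SE) on the log2 scale, from 132 ± 28.6 to 51.5 ± 9.75 normalized counts (SD, n = 4 each; limma adjusted p = 0.0225). Atoh8 (ENSMUSG00000037621), a basic helix-loop-helix transcription factor, fell by 0.98 ± 0.13, from 254 ± 31.9 to 129 ± 14.0 (limma adjusted p = 0.00325), and Cpm (ENSMUSG00000020183), a membrane carboxypeptidase, fell by 0.57 ± 0.07, from 569 ± 31.0 to 384 ± 35.3 (limma adjusted p = 0.00191). Ackr4 did not pass when any of vehicle replicates 1, 2 and 4 or S1P basal replicates 1, 3 and 4 was left out (adjusted p = 0.0690 to 0.163); over 23 alternatives its log2 change stayed between -1.49 and -1.16, with adjusted p up to 0.323. In each of these 3 genes all 4 basal S1P libraries lay below all 4 vehicle libraries. Ackr4 lies on chromosome 9 from 104084157 to 104126933, Atoh8 on chromosome 6 from 72206177 to 72235577, both on the minus strand, and Cpm on chromosome 10 from 117629500 to 117687352 on the plus strand. The next genes by p did not pass: Casz1, a zinc finger transcription factor, had a log2 change of -1.20 ± 0.21 (adjusted p = 0.0523), and Nuak1, a kinase, of -0.37 ± 0.07 (adjusted p = 0.139).

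Among the gene lists, 12 of 33 were called at the preset correlation for basal S1P against vehicle, and 0 with an estimated correlation, where the smallest adjusted p was 0.562. Of the interferon response genes 30 of 31 had lower means with basal S1P, with a median log2 change of -0.24 (adjusted p = 4.5e-07 preset and 0.562 estimated). Over all genes 0 of them were called, and 2 lower members were called when adjusted over the list alone. Gbp3, an interferon-induced GTPase, had a log2 change of -0.45 ± 0.12, and the transcription factor Irf1 of -0.23 ± 0.07. In the list of NF-kB targets, chemokines and leukocyte adhesion 20 of 25 were lower, among them the adhesion molecules Icam1 (-0.34 ± 0.11) and Selp (-1.17 ± 0.45), with adjusted p = 0.562 under an estimated correlation and 0 members called on either adjustment. Of the nuclear oxidative phosphorylation genes 33 of 33 were higher, with a median of 0.16, and 42 of 43 cytosolic ribosomal proteins, with a median of 0.15, neither with a called member and both with an adjusted p of 0.562 under an estimated correlation. By the steps in the values, 1 read was worth an estimated 0.8285 to 1.0015 normalized counts in vehicle and 0.8875 to 1.1505 with basal S1P. Higher means of compressed abundant genes, here and in the lists below, may therefore follow these library factors, which was not tested. Of the antigen presentation genes 13 of 15 were lower, among them the peptide transporter Tap1 (-0.20 ± 0.09), with 0 called.

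Other called lists had higher means with basal S1P, all with an adjusted p of 0.562 under an estimated correlation and with 0 members called over all genes. Of the MRTF and SRF targets, genes of the actin cytoskeleton and adhesion, 22 of 24 were higher, among them the integrin Itga5 (0.13 ± 0.05) and the myosin Myh9 (0.13 ± 0.06). Of the unfolded protein and integrated stress response genes 20 of 24 were higher, with 1 called when adjusted over the list alone, and Psat1, an enzyme of serine synthesis, was at 0.35 ± 0.10. In the hypoxia and glycolysis list 16 of 23 were higher, among them Ankrd37 (0.40 ± 0.14) and the carbonic anhydrase Car9 (0.54 ± 0.21). In the coagulation and fibrinolysis list 12 of 17 were higher, among them the urokinase receptor Plaur (0.39 ± 0.18) and the plasminogen activator Plat (0.32 ± 0.18). Of the adherens junction genes 13 of 18 were higher, including Jup, which encodes plakoglobin (0.31 ± 0.10), and of the caveolar and vesicular transport genes 14 of 18, including Cavin3 (0.24 ± 0.07), with 1 caveolar gene called when adjusted over the list alone. In the matrix and protease list 26 of 36 were higher, among them the integrin Itgb3 (0.25 ± 0.10). The 3 gene calls rested on the spread pooled over all 5 wild-type groups: a fit on only the 8 libraries compared called 0 genes. In the planned fit over all 20 wild-type libraries 640 genes had an unadjusted p under 0.05. Independent libraries without a change would give 612, but most libraries of one number were not independent, so 612 is no yardstick here.

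**Figure D2:**
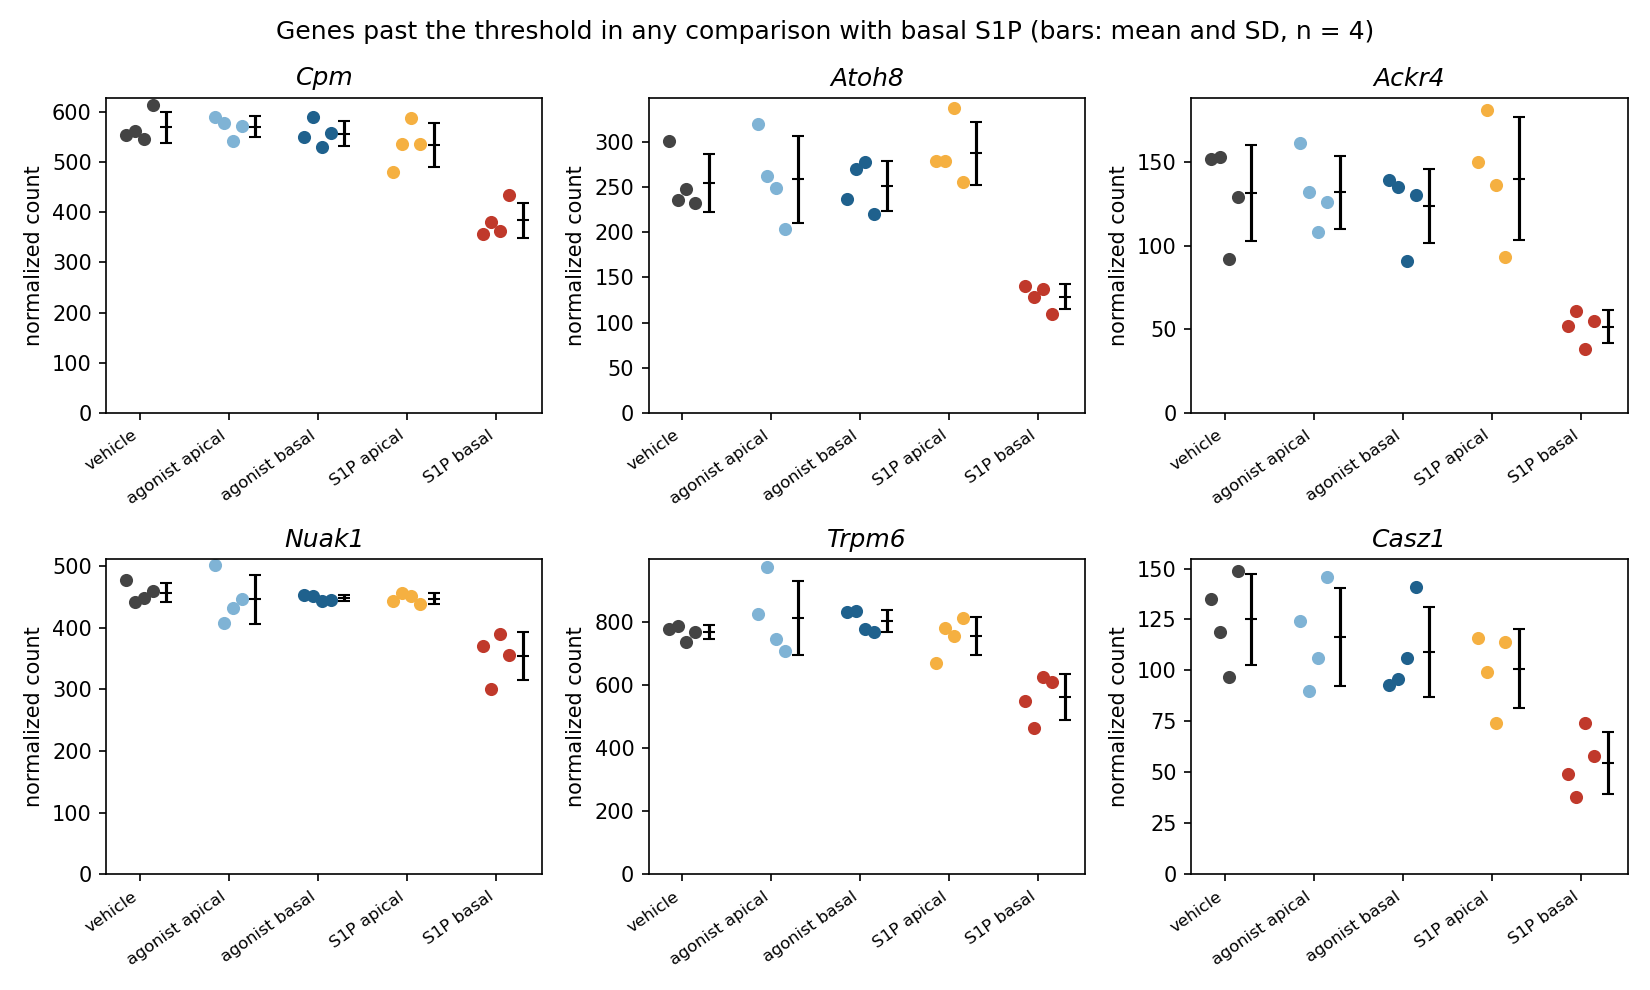
Normalized counts of the 6 genes past the threshold in any comparison, in each wild-type library (points), with group mean and SD beside them (n = 4); axes start at 0. In Ackr4 the basal S1P mean is 51.5, and the other 4 group means lie between 124 and 140.

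The side on which S1P was given was compared directly. The same genes were lower with basal than with apical S1P: Ackr4 by a log2 change of -1.41 ± 0.21 (limma adjusted p = 0.0106), Atoh8 of -1.15 ± 0.13 (adjusted p = 0.00057) and Cpm of -0.48 ± 0.07 (adjusted p = 0.0106), each in 4 of 4 libraries. Their means with apical S1P were 140.0 ± 36.5, 288 ± 34.9 and 535 ± 43.7 (SD, n = 4), near those of vehicle. Members of the BMP and TGF-beta list had opposite signs: Id2 (-0.89 ± 0.21), Bmp6 (-0.51 ± 0.12) and Smad6 (-0.34 ± 0.13) were lower and Bmp2 (1.10 ± 0.33) higher, none past the threshold over all genes, with 2 lower and 1 higher called when adjusted over the list alone. In the matrix and protease list 23 of 36 genes were higher, among them Adamts4 (0.91 ± 0.25) and Mmp14 (0.40 ± 0.16), without a call for any member. Of the cholesterol biosynthesis genes 21 of 24 were higher, with 0 called. All 11 tested pericyte markers had lower means with basal than with apical S1P, with a median log2 difference of -0.75 and 0 called, and Rgs5 was at -1.08 ± 1.04. Their sums were 2543, 1745, 1166 and 350 in S1P basal replicates 1 to 4, and 3091, 2441, 1940 and 1031 in S1P apical. S1P apical replicates 3 and 4 and S1P basal replicate 2 did not match their numbers by Xist, so side and set of cells cannot be told apart here. Of the 33 lists 6 were called at the preset correlation and 0 with an estimated one (smallest adjusted p = 0.792). Only 1 of the 3 genes kept its call without S1P apical replicate 3 and S1P basal replicate 2, and 1 gene was called on the 8 libraries alone or without any of S1P apical replicates 2 and 3 and S1P basal replicates 1 and 3.

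Basal S1P was then set against the 3 barrier-tightening treatments together, which lie on both sides and use both compounds. There were 6 genes lower with basal S1P and 0 higher. Besides Ackr4 (-1.33 ± 0.17, limma adjusted p = 0.00134), Atoh8 (-1.04 ± 0.11, adjusted p = 0.000132) and Cpm (-0.53 ± 0.06, adjusted p = 0.000132), these were Trpm6, a magnesium-permeable channel (-0.49 ± 0.08, adjusted p = 0.0165), Nuak1 (-0.34 ± 0.06, adjusted p = 0.0329) and Casz1 (-0.99 ± 0.17, adjusted p = 0.0329). Trpm6 was at 561 ± 72.7 normalized counts with basal S1P and at 754 ± 60.8 to 812 ± 117 in the 3 other treatments, and Nuak1 at 354 ± 38.7 against 446 ± 39.8 to 448 ± 4.43 (SD, n = 4 each). Casz1 was below every tightening library in 3 of 4 basal S1P libraries, and the other 5 genes in 4 of 4. Of the interferon response genes 29 of 31 were lower, with 0 called over all genes and 3 when adjusted over the list alone, among them Gbp3 (-0.45 ± 0.10). Bmp6 (-0.52 ± 0.10, adjusted p = 0.0579) and Id2 (-0.87 ± 0.17, adjusted p = 0.0635) did not pass over all genes, and 2 lower members of their list were called when adjusted over the list alone. In the Wnt list Reck (-0.28 ± 0.06) and Foxf2 (-0.20 ± 0.06) were among the members with the smallest p, with 0 called over all genes and 2 lower members when adjusted over the list alone. In the list of NF-kB targets 1 lower member was called when adjusted over the list alone, and Icam1 had a log2 change of -0.40 ± 0.09 (adjusted p = 0.151). Of the lists 8 were called at the preset correlation and 0 with an estimated one (smallest adjusted p = 0.810). The count was 3 when only the 4 treated groups entered the fit and 3 without S1P basal replicate 1. Without S1P apical replicate 3 and S1P basal replicate 2 there were 8 genes, which included 3 of these 6. Trpm6, Casz1 and Nuak1 lost their calls in 4, 12 and 14 of 31 alternatives.

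The agonist and apical S1P comparisons ask whether barrier-tightening treatments share a response. No gene passed the threshold in limma with apical agonist, basal agonist or apical S1P against vehicle. At an unadjusted p under 0.05 there were 134, 38 and 122 of 12249 genes. Independent libraries without a change would give 612. Libraries of one number were not independent, so 612 is not the count to expect without a change here. With apical agonist the smallest p belonged to Piezo1, a mechanically gated channel, at 0.15 ± 0.05 on the log2 scale, and with basal agonist to Hoga1 at -0.97 ± 0.30; with apical S1P it was Fbxo33 at -0.34 ± 0.10, and none of these passed. Of the list members, the 26 endothelial markers had higher means in 24 cases with apical agonist, 25 with basal agonist and 20 with apical S1P, and of the 43 ribosomal proteins 43, 43 and 42 were higher than in vehicle. In these 3 groups 1 read was worth an estimated 0.989 to 1.1405, 0.898 to 1.1685 and 0.9755 to 1.0885 normalized counts. In vehicle it was worth 0.8285 to 1.0015, so higher means of compressed abundant genes may follow these library factors, which was not tested. At the preset correlation 16, 14 and 11 lists were called, and with an estimated correlation 0 in each (smallest adjusted p = 0.140, 0.270 and 0.630). Of the interferon response genes 25 of 31 were higher with apical agonist, 24 lower with basal agonist and 28 lower with apical S1P. Smooth muscle markers were higher with apical S1P in 9 of 11 cases, with a median of 0.52, and pericyte markers in 10 of 11, with a median of 0.48. The summed pericyte markers were at 3091, 2441, 1940 and 1031 in S1P apical replicates 1 to 4, and at 3069, 2429, 1376 and 355 in vehicle. S1P apical replicates 3 and 4 did not match their numbers by Xist, so treatment and set of cells cannot be told apart here. Agonist apical replicate 2 did not match its number by Xist either, which limits the apical agonist comparison in the same way. The agonist and apical S1P comparisons share the vehicle libraries. Basal agonist did not differ from apical agonist in any gene (61 at an unadjusted p under 0.05), and 8 lists were called at the preset correlation and 0 with an estimated one. S1P and the agonist were given at different doses, 50 and 500 nM, so their responses are set side by side without a matched dose.

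The fold changes of different treatments against vehicle correlated across genes with r from 0.298 (basal agonist and apical S1P) to 0.498 (apical agonist and basal S1P). Unchanged groups of independent libraries simulated against shared vehicles gave 0.498, with a covariance of 0.0266, but libraries of one number were not independent. With deviations exchanged among libraries of one number, which leaves no treatment effect, 100 draws gave a mean r of 0.493 (from -0.747 to 0.886 over single pairs) and a mean covariance of 0.0156, and the observed covariances were 0.00692 to 0.0173. With the vehicle libraries split between both treatments, the mean r over splits ranged from -0.311 to -0.0715 (-0.270 on average in the exchanged libraries) and single splits from -0.649 to 0.175. With 1 library left out r ranged from -0.00221 (basal agonist and basal S1P, without agonist basal replicate 3) to 0.725. Genes are not independent replicates, and shared calls could not be assessed, since only basal S1P had called genes.

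The knockout libraries were read beside wild-type vehicle as values only. Endothelial genes were abundant in both: Pecam1 was at 73762 ± 2525 and Cldn5, the main claudin of brain endothelium, at 15013 ± 1612 normalized counts in knockout, and at 2507 ± 157 and 868 ± 82.1 in wild type (SD, n = 4 each). The ratio between the tables was far from constant. Actb was at 70931 ± 10215 against 1290 ± 99.7, and Cpm at 902 ± 56.2 against 569 ± 31.0. Col1a1 and Rgs5 were low in knockout, at 7 ± 7.70 and 51.2 ± 6.85, where wild-type replicates ranged from 12 to 260 and from 29 to 358. Xist was at 2, 10209, 3796 and 1438 in the knockout replicates. No value in the wild-type table exceeded 0.943 per exonic base, while values in the knockout table reached 154, so levels of abundant genes cannot be compared between genotypes from these tables. Changes of abundant genes between the wild-type groups may be understated for the same reason, and small ones may follow the library factors instead. In vehicle replicates 1 to 4 the abundant gene Eef1a1 was at 717, 739, 835 and 859 normalized counts. The estimated value of 1 read rose in the same order, at 0.8285, 0.8695, 0.9525 and 1.0015 normalized counts.

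**Figure D3:**
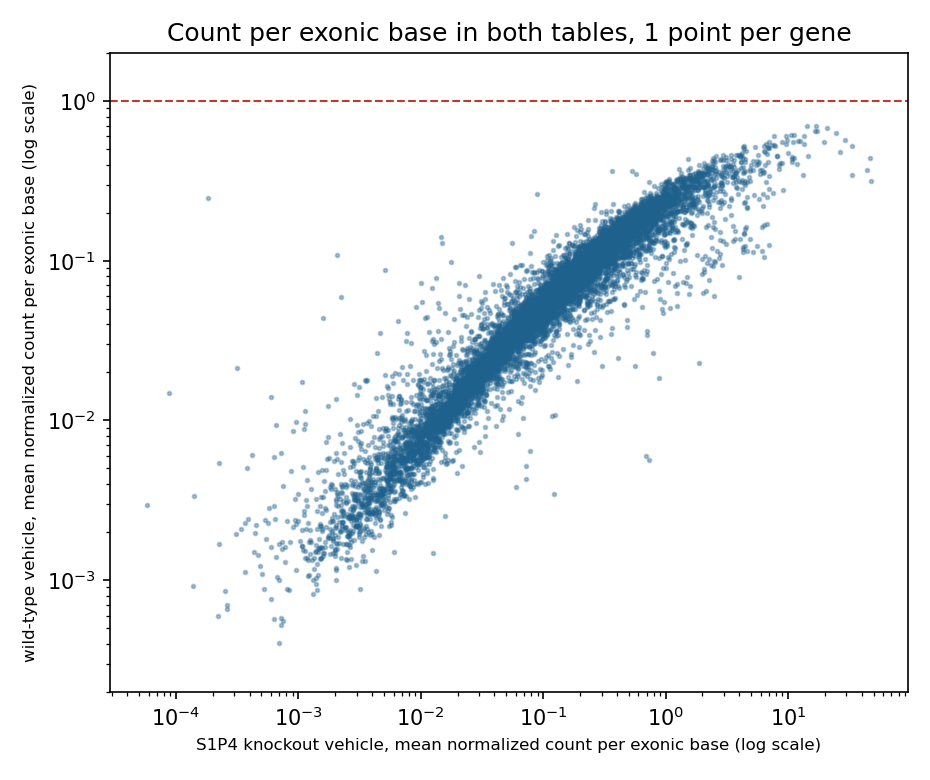
Mean normalized count per exonic base of each of 12224 genes in knockout vehicle (x axis) and wild-type vehicle (y axis), both on log scales, with a dashed line at 1 per base. There were 744 genes above 1 per base in knockout and 0 in wild type.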

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

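The tests of explanations and the splits in this part were chosen after the results were seen; the comparison of the sides was planned. The response to S1P differed between the basal and the apical side in 3 genes by a direct limma test: Cpm (-0.479 on the log2 scale), Atoh8 (-1.15) and Ackr4 (-1.41).

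For lower Ackr4, Atoh8 and Cpm under basal S1P against vehicle, another cell set in the doubted libraries (S1P basal replicate 2 and S1P apical replicate 3) is argued against, since all 3 genes stayed past the threshold without both, and scaling of the libraries as well, because 3 genes stayed under both library totals and quantile normalization. Against apical S1P the calls of Cpm and Ackr4 ended without both libraries, with fewer libraries and wider SE (Cpm from -0.48 ± 0.07 to -0.43 ± 0.08, Ackr4 from -1.41 ± 0.21 to -1.49 ± 0.25). All 3 genes stayed at least 5.55 SE below 0, in a test that replaced a count of kept calls (1 of 3). The genes had been picked for large changes in the full set of libraries, so this test could hardly fail. The similar fold changes show only that the difference did not rest on both libraries alone. For fewer mural cells or fibroblasts against vehicle, a first test on summed markers (-0.0779 ± 0.114, SD over 4 same-numbered pairs) was set aside, because number 2 did not pair and pericyte markers alone changed by -0.252 ± 0.187, and a second because it could only repeat the calls; with the sums of pericyte, smooth muscle and fibroblast markers as covariates all 3 genes stayed called and at least 7.98 SE below 0, which argues against these cells as the whole cause. Against apical S1P the pericyte markers fell too (median -0.752, which alone left this open), but in a later test with their sum as covariate all 3 genes stayed called and at least 6.41 SE below 0 (Cpm -0.50 ± 0.07), which argues against fewer pericytes as the whole cause, while chance is not excluded for that comparison in the planned fit. Of the 35 splits of the 8 libraries with vehicle and basal S1P only 1, the real one, gave as many genes (3, against at most 0 in the others), which argues against chance. The splits exchange libraries across replicate numbers, though, and most same-numbered libraries were not independent, so fewer than 35 splits are comparable with the real one. A response to S1P at the basal side was not tested separately.

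S1P apical replicate 3 and S1P basal replicate 2 stood apart from the libraries with their numbers. Their deviations from the group means correlated at 0.662 with each other, and at no more than 0.400 and 0.381 with any other library, so both may have come from one further set of cells. A first test of swapped labels favoured a swap, since swapping them raised the lowest same-number correlation with vehicle over both S1P groups from 0.0291 to 0.132. A second test, chosen after the first was seen, argues against it more strongly, on genes called without these libraries: all 4 (Cpm, Bmp6, Atoh8 and Ackr4) were lower in S1P basal replicate 2, while the first result stays unexplained. No biological explanation was tested, and the record of which pool of mice gave each library would settle it.

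Abundant genes were compressed in the wild-type table. If reads at one position were counted once there, no gene could exceed about 1 per exonic base on 1 strand, and 0 genes did in any library, which is consistent with removal of duplicate reads before counting. Sequencing depth would shift all genes alike, but the median log2 ratio of knockout to wild type was 1.77 higher in the top than in the bottom 10% of genes by count per base (SD within the bottom 10% 0.869). Different gene models are argued against by a gap of 1.82 over the 8132 genes with equal coordinates. The handling of duplicates is not given in the sources used here. The genotype given by the labels is fully confounded with the table, so whether it adds to the gap of single genes stays open.

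Some single values stood outside the other 3 of their group. Among 173 groups of 4 values tested, 6 did, a smaller share than the 1 in 20 that chance alone gives. S1pr4 was 349 in knockout replicate 3 against 250 to 261 in the others, and Uty, a Y-linked gene, was 479 in knockout replicate 1 against 65 to 134. Gm29257 was 11 in vehicle replicate 1 against 10, a difference of 1, and 9 in S1P apical replicate 1 against 14 to 15. Gm45053 was 16 in agonist apical replicate 4 against 9 to 10, and Scp2-ps2 was 11 in agonist apical replicate 3 against 17 to 18. Mitochondrially encoded genes, which only the knockout table lists and no comparison used, took 2.36 ± 0.431% (SD, n = 4) of the knockout values.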

How the results depend on the processing

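The covariates and the omission of both doubted S1P libraries were chosen after seeing the data; the other alternatives were planned. Under library totals, quantile normalization, no filter, the CPM filter and both pseudocounts, Ackr4, Atoh8 and Cpm stayed called against vehicle, and no called gene reversed under any alternative. Against vehicle, apical S1P, and the tightening treatments in turn, basal S1P gave 47, 83 and 137 genes with the replicate block, for which the numbers do not pair these libraries throughout (the lowest same-number correlation was 0.0291 with vehicle, -0.345 with S1P apical and -0.0368 with agonist basal), 17, 12 and 61 with sex-linked genes as covariates, 6, 5 and 21 with the summed pericyte markers as covariate, and 11, 15 and 100 with those of pericytes, smooth muscle and fibroblasts. With components as covariates the counts were 9, 10 and 45 for 1, 97, 102 and 272 for 2, 356, 333 and 685 for 3, 395, 302 and 253 for 4, 7, 0 and 0 for 5, and 0 throughout for 6. Treatment group accounted for 83.1% of the scores of component 4 and for 5.14 to 12.0% of those of components 1 to 3, and component 4 separated all basal S1P libraries (-15.4 to -8.97) from the others (-2.19 to 10.4), so fits with 4 or more components take out part of the effect tested and do not measure robustness. Agonist basal against vehicle gave 1 gene with 5 components. Only the groups compared gave 0, 1 and 3 genes, a change of at least 1.5 times 2, 2 and 3 (Cpm fell by less against vehicle and apical S1P), and omission of both doubted libraries 1 against apical S1P. Fewer libraries enter the fits of only the groups compared, and the cause of the other differences was not tested. Leaving out 1 replicate gave 2 to 4 genes against vehicle, 1 to 3 against apical S1P (1 without S1P apical replicate 2 or 3 or S1P basal replicate 1 or 3) and 3 to 9 against the tightening treatments (3 without S1P basal replicate 1), and 0 for the agonist comparisons and apical S1P. Ackr4 lost its call against vehicle without vehicle replicate 1, 2 or 4 or S1P basal replicate 1, 3 or 4, with a highest adjusted p of 0.323 (only the groups compared) over the alternatives with fewer than 4 components. With 3 components, leaving out 1 replicate gave 203 to 307, 125 to 299 and 371 to 761 genes (lowest without S1P basal replicate 4, 2 and 2; 210 without vehicle replicate 4, 157 without S1P apical replicate 4, 412 and 378 without S1P basal replicate 1 and 4), and omission of both doubted libraries 178, 155 and 178. List calls of the planned fit ended in all 7 comparisons (0 lists) with an estimated correlation, while with 3 components 1 list kept its call in each comparison of basal S1P (adjusted p = 0.00269, 0.00208 and 0.00107); against apical S1P 6 lists became 10 with the block, 3 with the CPM filter and 12 with 3 components, and with 3 components apical S1P against vehicle and basal against apical agonist gave 5 lists each. Splitting the vehicle libraries reversed the sign of r, as a mean over splits, for the effects of apical with basal agonist (-0.299), apical agonist with apical S1P (-0.187) and with basal S1P (-0.108), basal agonist with apical S1P (-0.311) and with basal S1P (-0.202), and apical with basal S1P (-0.0715). Single splits ranged from -0.649 to 0.175, and the highest was positive for every pair except apical with basal agonist (-0.0740). Libraries of one number are not independent, and with their deviations exchanged, so that no treatment effect is left, the mean over splits was -0.270, so negative values arise without a treatment effect. With 1 library left out r ranged, in the same order of pairs, from 0.187 to 0.725, 0.226 to 0.667, 0.109 to 0.725, 0.121 to 0.556, -0.00221 to 0.687 and 0.131 to 0.654. Alternatives that need raw counts (2 count models, voom and their size factors) and all planned fits across the 2 tables were not run. No paired analysis was made for knockout against wild type, since no test was made between the tables. They were normalized separately and used different gene models, and abundant genes were compressed in the wild-type table alone. Same-number correlations of knockout with wild-type vehicle were 0.226 to 0.534 over 12075 genes, and vehicle replicates 1 and 3 correlated best with another number. In the simulation 53.2% of 1.5-fold changes were recovered, so changes of that size are only partly detectable here. The simulated changes were placed on the compressed wild-type values, so how far changes in the RNA of abundant genes are detectable was not tested.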

Other observations

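The covariate fits, the set of genes below and the splits were chosen after the results were seen. With the first 3 principal components as covariates, 179 genes were higher and 177 lower with basal S1P than with vehicle, and 38 of these were also called with the replicate block, 10 higher and 28 lower. In simulated data with changed genes the block gave 4 to 11 false calls per repeat with library differences as observed and 3 to 13 with differences redrawn. A first definition of this set, which also required a call with 2 and with 4 components, left 16 genes and was widened after that was seen. The following log2 changes are from the fit with 3 components (SE beside them), and each gene was chosen for its known function after its value was seen. Lower genes included the adhesion molecules Selp (-0.73 ± 0.19) and Icam1 (-0.40 ± 0.06), the interferon-induced GTPases Gbp5 (-0.54 ± 0.06) and Gbp3 (-0.36 ± 0.05), the BMP target Id2 (-0.63 ± 0.10), the aryl hydrocarbon receptor Ahr (-0.58 ± 0.08) and its repressor Ahrr (-0.74 ± 0.17). Enpp2, which encodes the lysophospholipid enzyme autotaxin, was at -0.59 ± 0.06, and the ceramidase Acer2 at -0.49 ± 0.08. Higher genes included Crmp1 (0.88 ± 0.12), the aldo-keto reductase Akr1b8 (0.86 ± 0.11), the chloride channel Ano1 (0.50 ± 0.05), Jup (0.30 ± 0.04) and the integrin Itgb3 (0.18 ± 0.04). The list of NF-kB targets, chemokines and leukocyte adhesion was lower in this fit also with an estimated correlation (camera adjusted p = 0.00269), with 21 of 25 members lower, 9 called and 13 called when adjusted over the list alone. It was also lower against apical S1P (adjusted p = 0.00208) and the tightening treatments (0.00107). In the planned fit the same list had an adjusted p of 0.562 against vehicle.

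How many genes respond to basal S1P, and which, may not be settled by these libraries. The count against vehicle was 3 in the planned fit, 9 for 1 component, 97 for 2 and 356 for 3. Fits with 4 to 6 components do not bear on this, since component 4 separates basal S1P from the other groups. With library differences kept as observed, simulated data gave the fit with 3 components a recovery of 81.2% of 1.5-fold changes, but 8 to 22 false calls per repeat. With differences redrawn it recovered 15.2% and, at 4-fold, 29.6%, with 0 to 16 false calls. With no gene changed it gave 0 calls in both simulations. With the same 3 components, other splits of the libraries gave at most 1 gene against vehicle (356 in the real one, 1 of 35 splits), 18 against apical S1P (333, 1 of 35) and 25 against the tightening treatments (685, 1 of 100 drawn). This argues against chance for these counts, although 35 splits allow no share below 1 of 35 and exchange libraries across replicate numbers. The splits leave the choice of 3 components open, which was made after the results were seen.

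In the planned fit, 3 genes differed against apical S1P, as many as 2 of 35 splits gave, and 1 split called 1405 (S1P apical replicates 1 and 2 with S1P basal replicates 1 and 4, against the rest), which points to a structure of the libraries. Chance is therefore not excluded in that fit, while with 3 components this split called 0. Against the tightening treatments 1 of 100 draws gave 6 genes, the real one, with at most 0 in the others, which argues against chance. For the comparisons with 0 genes in limma (134, 38, 122 and 61 at an unadjusted p under 0.05 for apical agonist, basal agonist, apical S1P and the agonist sides) no split of the 35 can give fewer, so the splits decide nothing. The highest of the other splits was 0, except 1151 for basal agonist, from replicates 1 and 2 against 3 and 4 of both groups, which points to a structure of the libraries. The splits exchange libraries across replicate numbers. Chance is not excluded for any list count of the planned fit: as many lists were called in 5 of 35 splits for apical agonist (16, at most 20 otherwise), 8 for basal agonist (14, at most 23), 8 for apical S1P (11, at most 15), 10 for basal S1P (12, at most 18), 22 for basal against apical S1P (6, at most 12), 24 for the agonist sides (8, at most 19) and 55 of 100 for the tightening treatments (8, at most 20).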
